A study of Caenorhabditis elegans with 4 samples.

How the data were processed

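Whole early adult Caenorhabditis elegans were profiled by mRNA sequencing in 4 libraries, 2 of the wild-type strain N2 and 2 of the strain carrying fasn-1(g14), a mutant allele of the gene for fatty acid synthase. Per the labels' protocols, embryos released by bleach were held at 1 egg per µl in buffer without food for 8 days at 20 °C, so that the hatchlings stayed in L1 arrest, the halt of development that follows hatching without food. Per the same protocols, 750 live animals were then put on plates with HT115 bacteria carrying an empty vector, with 25 µg/ml carbenicillin and 1 mM IPTG, and were washed off about 68 hours later, when eggs were seen. Per the labels' protocols, RNA was taken with TRIzol and acid-washed sand, and each library was made from 1 µg of total RNA with the NEBNext Ultra II RNA kit and 8 PCR cycles. This kit does not mark the strand, so reads of a gene and of an overlapping gene on the other strand cannot be told apart. The design text describes the replicates as biological. Read length and sequencer are not given in the sources used here.

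The deposited values are a normalized signal per gene in CPM, reads scaled to library size, as the authors named the table, with 1 column per library and 1 row per sequence name. Per the submitters' processing notes, Bowtie2 2.3.3.1, HTSeq 0.12.4 and edgeR 3.28.1 were used, without the role or settings of each. The genome build, the annotation and the rule by which genes were kept are not given in the sources used here. The deposited columns sum to between 0.942 and 1.03 times the nominal CPM total, as CPM computed with normalization factors do. Each positive value was a whole multiple of the smallest step of its column within a tolerance of 0.001 read, for 100% of values in each of the 4 libraries. From these steps the reads per gene were recovered, and the factors implied by the deposited CPM lay between 0.972 and 1.06. A further 8 columns of libraries in the table belong to other samples and were not used. The table holds 13758 rows. Of these, 13747 matched 1 gene by the transcript identifiers of the Ensembl release 115 annotation of WBcel235, 8 had no match, and 3 had an ambiguous name, with 2 of the rows sharing the sequence name ZC416.8. The annotation served for gene names and positions, and whether it is the build of the authors is not known.

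Groups were taken from the sample titles. The comparison, its test, the gene lists, the rule for named genes and all alternatives except the one named as added in the closing part were chosen before the data were examined. The design fixed a test for CPM values, and that test was used on the normalized signal without further scaling. Genes with at least 1 CPM in at least 2 libraries were tested, which left 12977 genes and removed 781 rows. limma 3.58.1 was fitted in R 4.3.3 to log2(CPM + 1) with group as the term, with a mean-variance trend in the empirical Bayes step, as a two-sided test. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes on the log2 scale are therefore changes of log2(CPM + 1), mutant minus wild type, and understate the change of low genes. Folds without "log2" are ratios of mean normalized CPM. Errors of levels are SD over 2 libraries, and errors of log2 changes are standard errors of the fit (SE).

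A set of 36 gene lists, drawn up from general knowledge of the organism, was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it, and members were also counted after adjustment over the list alone. The list of genes of the mitochondrial genome was matched by chromosome, because the annotation gives those genes other symbols. Some genes stand in more than 1 list. Named genes are fasn-1; the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, with at least 5 CPM in the higher group and a gene symbol of letters and number; up to 4 members of each list with the smallest p-values and a mean of at least 1 CPM; and the yolk genes vit-1 to vit-6 with rme-2. From 298 rises and 685 falls that met the conditions, the 12 largest of each were taken. Other genes are marked as chosen after their values were seen.

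The recovered reads came to 15023519 and 13960509 in wild type replicates 3 and 4, and to 14643426 and 15889424 in mutant replicates 3 and 4. One read was worth between 0.0628 and 0.0676 CPM, so 3 reads, the floor used here, stood at 0.188 to 0.203 CPM. Read counts without molecular identifiers are not independent molecules, and the floor covers counting error only. Replicates were compared before averaging. A chi-square of their recovered reads, over genes with at least 20 reads, was 4.58 times its degrees of freedom in wild type and 13.3 times in the mutant, so no library repeated another.

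The test was tried on simulated data drawn from the real means and library sizes, in 3 runs with 12767 to 12803 genes tested. For this comparison, 41.3% of 150 genes changed by 1.5-fold were recovered, 74% of 150 at 2-fold, 100% of 150 at 4-fold and 100% of 150 at 8-fold. The changed genes had a mean of at least 5 CPM, so recovery of lower genes was not tried. Both groups were given the same dispersion, though the mutant replicates differed more. Of the 579 calls in these runs, 68 were false, above the share set by the threshold, and 0 had the wrong sign. The 3 runs without changed genes gave 15 false calls in all. A simulated list of 30 genes raised by 1.5-fold was called in 3 of 3 runs, and 0 unchanged lists were called. Genes were drawn independently of each other, so the runs do not show how the list test behaves for genes that vary together. In the real lists the correlation estimated by camera reached 0.96 for oocytes and 0.778 for neurons.

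Alternatives were a pseudocount of 0.5 or 5 CPM, no filter on low values or a mean of at least 5 CPM, rescaling by TMM, median ratio or upper quartile, the empirical Bayes step without the trend or with its robust form, each library left out in turn, the replicate number as a block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and the other list tests. Figures were drawn with matplotlib 3.10.9 from tables handled in Python 3.11.15 with pandas 2.3.3. GC content was not examined, since no genome sequence was used here.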

Results

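Gene expression after a long larval starvation was compared between wild-type C. elegans (N2) and animals carrying fasn-1(g14), an allele of the fatty acid synthase gene. The series title names the subject as early adults of a fatty acid synthesis mutant after extended L1 arrest, and both groups had been starved as hatchlings. There were 2 biological replicates per group, numbered 3 and 4. The recovered depth was 15023519 and 13960509 reads in the wild-type libraries and 14643426 and 15889424 reads in the mutant libraries. The 10 most abundant genes took 9.51% and 10.0% of the wild-type signal, and 14.04% and 13.62% of the mutant signal.

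The mutated gene itself, fasn-1 (F32H2.5, WBGene00009342; chromosome I, 8975366 to 8986540, minus strand, WBcel235), was measured at 369 and 410 CPM in wild type and at 353 and 285 CPM in the mutant. Its log2 fold change of -0.29 (SE 0.11, 95% interval -0.56 to -0.03) did not pass the test (limma, adjusted p = 0.1196), so the level of the transcript did not check the genotype labels. Across the genome, 572 genes rose and 1386 genes fell in the mutant among 12977 tested (limma, Benjamini-Hochberg adjusted p below 0.05). Those that fell included 13 of 17 pharynx, 27 of 39 neuron and 12 of 34 molting genes, and those that rose included 33 of 52 sperm, 5 of 7 yolk, 10 of 27 fatty acid synthesis and 8 of 26 sphingolipid metabolism genes. Of the calls, 188 rises and 1002 falls reached 2-fold on the log2(CPM + 1) scale. The groups did not overlap for 64.04% of tested genes, against 33.3% by chance. The mutant libraries differed from each other more than the wild-type libraries did, with a Pearson correlation across genes of 0.988 against 0.995. On the first principal component, which held 83.5% of the variance, wild type lay at -29.8 and -37.6, mutant replicate 3 at 17.5 and mutant replicate 4 at 49.9. The counts depended on single libraries: 152 genes rose and 179 fell without wild type replicate 4, 151 and 445 without wild type replicate 3, 996 and 1811 without mutant replicate 4, and 2346 and 3268 without mutant replicate 3. In each of these fits 1 group had a single library, which was assumed to vary like the pair in the other group.

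The pharynx list had the lowest median of the 36 lists. Of 17 measured, 13 fell, 0 rose and 4 did not pass, with a median log2 change of -2.15, and 14 fell when adjusted over the list alone. The pharyngeal myosin heavy chains myo-1 and myo-2 stood at 401 ± 3.69 and 416.9 ± 12.7 CPM in wild type and at 76.9 ± 31.7 and 73.5 ± 43.5 CPM in the mutant (limma, adjusted p = 0.00308 and 0.00778). The pharyngeal troponin I gene tni-4 fell from 103.8 ± 9.95 to 21.8 ± 9.50 CPM, and marg-1 fell from 28.4 ± 0.829 to 4.38 ± 0.974 CPM. The pharyngeal troponin T gene tnt-4, among the 12 largest falls of all genes, went from 164 ± 31.7 to 23.7 ± 19.8 CPM. Against the wild-type mean, the list median was -1.34 in mutant replicate 3 and -2.65 in mutant replicate 4. As a set the pharynx list was lower by limma's camera (adjusted p = 2.68e-08), a call not kept by the same test with its own correlation (adjusted p = 0.589 with an estimated correlation).

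Of 39 neuronal genes measured, 27 fell, 0 rose and 12 did not pass, with a median log2 change of -1.18, and 33 fell when adjusted over the list alone. The enzymes and helpers of neuropeptide processing were among those with the smallest p-values. The proprotein convertase gene egl-3 fell from 99.1 ± 1.67 to 42.4 ± 7.64 CPM, its chaperone sbt-1 from 51.9 ± 5.597 to 19.3 ± 4.37 CPM, and the amidating lyase pgal-1 from 46.6 ± 0.456 to 18.7 ± 0.378 CPM (limma, adjusted p = 0.00421, 0.00729 and 0.00267). The neuropeptide gene flp-14 fell by 1.93 on the log2 scale (SE 0.24). The list medians of the mutant libraries were -0.85 in replicate 3 and -1.45 in replicate 4. Without wild type replicate 4, 10 neuron genes and 6 pharynx genes fell, and without wild type replicate 3 these counts were 17 and 9. The neuron list was lower by camera (adjusted p = 1.86e-15; adjusted p = 0.599 with an estimated correlation). Insulin-like peptide genes, most of them expressed in neurons, had 3 falls, 0 rises and 10 members that did not pass (median -0.64), and 5 fell when adjusted over the list alone. Of these, daf-28 fell from 6.41 ± 1.33 to 1.93 ± 0.526 CPM and ins-18 from 2.44 ± 0.0767 to 0.594 ± 0.0756 CPM. The set was lower by camera (adjusted p = 0.00173; adjusted p = 0.589 with an estimated correlation), and 0 of its members passed without either wild-type library, against 6 without mutant replicate 3. In the steroid hormone and dauer list, 5 of 26 genes fell and 1 rose, against 5 and 2 when adjusted over the list alone. Without wild type replicates 3 and 4 in turn 2 and 1 of them fell, and without mutant replicates 3 and 4 in turn 6 and 3 rose. There daf-7, a TGF-beta ligand made in sensory neurons, fell from 12.2 ± 2.04 to 1.53 ± 0.514 CPM (limma, adjusted p = 0.00491), the nuclear receptor gene daf-12 fell by 0.63 on the log2 scale, and the insulin receptor gene daf-2 rose by 0.29. That list as a whole was not called (camera, adjusted p = 0.818).

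**Figure D1:**
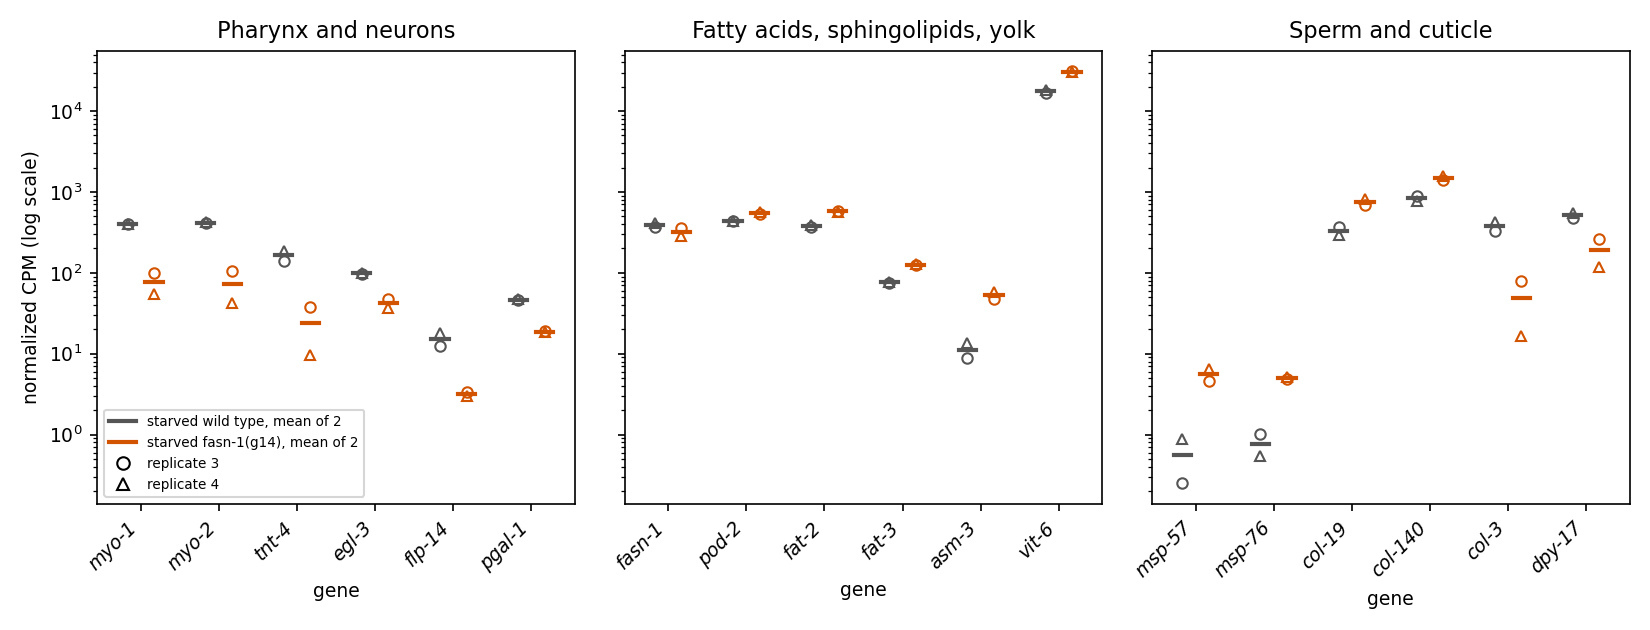
Normalized CPM (log axis) of 18 genes in each of the 4 libraries, with circles for replicate 3, triangles for replicate 4 and a bar at the mean of each group. The mutant libraries lie below wild type for the pharynx and neuron genes shown, and for myo-2 they stand at 104.3 and 42.8 CPM against 408 and 426 CPM.

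In body wall muscle the members moved both ways. Of 31 measured, 11 fell, 3 rose and 17 did not pass, with 14 falls and 3 rises when adjusted over the list alone. The attachment and filament genes deb-1 (vinculin), unc-52 (perlecan), mup-2 (troponin T) and myo-3 (myosin heavy chain) fell by 0.89, 0.84, 0.75 and 0.77 on the log2 scale (SE 0.11, 0.11, 0.08 and 0.11). The 3 that rose, named after their values were seen, were tnt-2 (troponin T), unc-27 (troponin I) and atn-1 (alpha-actinin), by 0.53, 0.36 and 0.32. Falls numbered 5 without either wild-type library and 19 without mutant replicate 3, and 1 and 0 muscle genes rose without wild type replicates 3 and 4. The list was lower by camera (adjusted p = 0.00111; adjusted p = 0.722 with an estimated correlation). The intestine list had 8 rises, 2 falls and 23 of 33 members that did not pass, and 10 rises and 2 falls when adjusted over the list alone. Genes of lysosomal and digestive proteases led them: cpr-6 rose 1.65-fold from 612 ± 38.1 to 1013 ± 55.2 CPM, cpr-1 1.70-fold, asp-13 1.71-fold and asp-4 1.45-fold (limma, adjusted p = 0.00630, 0.00544, 0.00699 and 0.0109). Intestinal rises numbered 5 and 3 without wild type replicates 3 and 4, with 0 falls, and 15 without mutant replicate 3, with 4 falls. Camera called the intestine list higher (adjusted p = 0.00111; adjusted p = 0.589 with an estimated correlation).

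In the list of fatty acid synthesis, elongation and desaturation, 10 of 27 genes rose, 0 fell and 17 did not pass, with a median log2 change of 0.34, and 16 rose and 3 fell when adjusted over the list alone. The desaturase genes fat-2, fat-3 and fat-4 rose to 579 ± 7.65, 127 ± 1.32 and 277 ± 3.88 CPM, 1.51-fold, 1.67-fold and 1.37-fold above wild type (limma, adjusted p = 0.00736, 0.00465 and 0.0124). The acyl-CoA dehydratase gene hpo-8 rose 1.49-fold. The acetyl-CoA carboxylase gene pod-2, named after its value was seen because its product feeds fatty acid synthase, rose by 0.34 on the log2 scale (adjusted p = 0.0262). Without wild type replicates 3 and 4 in turn, 3 and 2 genes rose, and without mutant replicate 3 there were 19 rises and 3 falls. This list was higher by camera (adjusted p = 4.25e-06; adjusted p = 0.589 with an estimated correlation). Sphingolipid genes had 8 rises, 1 fall and 17 members that did not pass (median 0.22), or 10 rises and 2 falls when adjusted over the list alone. The acid ceramidase genes asah-1 and asah-2 rose 2.26-fold and 2.23-fold, and the glucocerebrosidase gene gba-4 rose 1.92-fold. The acid sphingomyelinase gene asm-3 rose 4.72-fold from 11.2 ± 3.46 to 52.8 ± 7.20 CPM (log2 change 2.17, SE 0.21; limma, adjusted p = 0.00314). Only 5 sphingolipid genes rose without either wild-type library, and 13 rose and 2 fell without mutant replicate 3. The sphingolipid list was higher by camera (adjusted p = 1.63e-04; adjusted p = 0.589 with an estimated correlation).

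The yolk protein genes, the most abundant transcripts of the adult intestine, were higher in both mutant libraries than in both wild-type libraries. Of 7 genes in the list, vit-1, vit-3, vit-4, vit-5 and vit-6 rose, and 6 rose when adjusted over the list alone. From vit-1 to vit-6 the wild-type means were 5085, 17422, 10511, 9794, 13659 and 17671 CPM, and the mutant means were 8094, 27900, 16329, 15415, 23394 and 30722 CPM. Neither vit-2 (log2 change 0.68, SE 0.19; limma, adjusted p = 0.0525) nor the yolk receptor gene rme-2 (0.23, SE 0.12; adjusted p = 0.241) passed. With the replicate number as a block 0 of the 7 passed, and with a pseudocount of 5 CPM 1 rose. Without either wild-type library 0 of the 7 passed, though their median log2 change was 0.62 and 0.70. The genes vit-1 to vit-5 are close copies of one another, and reads can be split among them. The yolk list was higher by camera (adjusted p = 1.63e-04; adjusted p = 0.589 with an estimated correlation and 0.0665 with the block).

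In fatty acid oxidation 5 of 43 genes rose and 2 fell, against 10 and 3 when adjusted over the list alone. Here hacd-1 and ech-7 rose 1.73-fold and 2.04-fold, acdh-8 rose by 1.33 on the log2 scale from a level near the floor, and the carnitine palmitoyltransferase gene cpt-3 fell by 1.67. Without wild type replicates 3 and 4 in turn 3 and 2 rose and 2 and 0 fell, against 15 and 7 without mutant replicate 3 and 9 and 2 without mutant replicate 4. This list was higher by camera (adjusted p = 0.00885; adjusted p = 0.589 with an estimated correlation). The glyoxylate, gluconeogenesis and trehalose list had 4 rises and 1 fall among 15 genes, or 8 and 2 when adjusted over the list alone. Its rises included the trehalase genes tre-2 and tre-3 (1.47-fold and 1.85-fold) and the trehalose phosphate phosphatase gene gob-1 (1.33-fold), while pck-1, for phosphoenolpyruvate carboxykinase, fell from 166 ± 8.75 to 98.4 ± 33.7 CPM. In this list 0 genes rose or fell without wild type replicate 3 and 1 rose without wild type replicate 4, whereas 9 rose and 2 fell without mutant replicate 3, and 7 and 2 without mutant replicate 4. Camera called it higher (adjusted p = 0.00779; adjusted p = 0.589 with an estimated correlation, 0.0747 without mutant replicate 3 and 0.107 with the block). Among genes of fat storage, lipases and lipid binding 3 rose and 2 fell of 32, or 5 and 2 when adjusted over the list alone. The lysosomal lipase genes lipl-1 and lipl-2 rose 3.58-fold and 2.79-fold, whereas lipl-6 and far-6 fell by 1.27 and 0.57 on the log2 scale, and the list was not called (camera, adjusted p = 0.0750; 0.0208 without mutant replicate 4). Rises there numbered 1 and 2 without wild type replicates 3 and 4, with 0 falls, and 11 and 8 without mutant replicates 3 and 4. For phosphatidylcholine synthesis and the methionine cycle the counts were 4 rises and 1 fall of 24, or 5 and 3 when adjusted over the list alone. The methyltransferase genes pmt-1 and pmt-2 rose 1.39-fold and 1.48-fold, and the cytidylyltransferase genes pcyt-1 and pcyt-2.1 rose 1.51-fold and 1.32-fold, with no call for the list (camera, adjusted p = 0.207), and 0 members passed without either wild-type library, against 8 rises without mutant replicate 3 and 6 falls without mutant replicate 4.

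Of 52 sperm genes measured, 33 rose, 0 fell and 19 did not pass (median log2 change 1.297), and 42 rose when adjusted over the list alone. The major sperm protein genes msp-57, msp-53 and msp-76 stood at 0.564 ± 0.442, 0.658 ± 0.309 and 0.772 ± 0.329 CPM in wild type and at 5.601 ± 1.33, 5.04 ± 1.297 and 5.06 ± 0.175 CPM in the mutant (limma, adjusted p = 0.0107, 0.0116 and 0.0107). In the library with the fewest reads of msp-57, wild type replicate 3, there were 4. The msp genes are near-identical copies, so reads cannot be assigned with certainty among them. Among the 12 largest rises of all genes, the sperm-specific gene ssq-4 and msrp-2 went from 0.928 ± 0.691 to 5.82 ± 2.21 CPM and from 0.639 ± 0.814 to 5.11 ± 1.01 CPM. Without wild type replicates 3 and 4 in turn, 5 and 14 sperm genes rose. As a set sperm genes were higher by camera (adjusted p = 1.73e-16; adjusted p = 0.589 with an estimated correlation). With a mean of at least 5 CPM required, 0 members passed in either direction and the median of those left was 0.19 (camera, adjusted p = 0.3303).

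In the oocyte and eggshell list 0 of 32 genes passed, over all genes or when adjusted over the list alone, with a median log2 change of 0.23; cpg-3, an eggshell proteoglycan gene, had 0.43 (SE 0.14; limma, adjusted p = 0.0694) and mex-6 had 0.30. The oocyte median was 0.07 in mutant replicate 3 and 0.40 in mutant replicate 4, and 29 genes passed without mutant replicate 3. For meiosis and the mitotic germline 0 of 42 passed by either adjustment (median 0.15), against 22 without mutant replicate 3, with zim-1 at 0.28 and gld-2 at 0.27. Both lists were higher by camera (adjusted p = 1.22e-05 and 1.71e-04), though not by the other form of the test (adjusted p = 0.741 and 0.757 with an estimated correlation) nor without mutant replicate 4 (0.0532 and 0.0807). In the cell cycle and DNA replication list klp-18, cdk-2 and cdt-1 rose 1.299-fold, 1.53-fold and 1.31-fold, 58 of 61 did not pass, and 0 passed when adjusted over the list alone, with 0 without either wild-type library and 24 rises without mutant replicate 3. It too was higher by camera (adjusted p = 8.41e-05; adjusted p = 0.722 with an estimated correlation). Early zygotic embryo genes had 0 of 28 past the threshold by either adjustment (camera, adjusted p = 0.818), and 9 falls without mutant replicate 3, with pal-1 at 0.25 and ceh-22 at -0.94. In the somatic gonad, uterus and vulva list 2 rose and 5 fell of 28, or 3 and 7 when adjusted over the list alone, among them inx-8 and nid-1, which rose 1.84-fold and 1.402-fold, and ceh-18 and egl-13, which fell by 1.08 and 0.73 on the log2 scale (camera, adjusted p = 0.457). There 1 and 0 fell without wild type replicates 3 and 4, and 11 fell and 8 rose without mutant replicate 3.

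Cuticle collagen genes moved in both directions. Among 122 measured, 23 rose, 35 fell and 64 did not pass, and 29 rose and 55 fell when adjusted over the list alone. The genes that rose had a median wild-type level of 331 CPM, and those that fell had a median of 43.8 CPM, with no test of level against direction. The adult collagen gene col-19 rose 2.29-fold from 331 ± 53.5 to 760 ± 95.1 CPM, col-140 rose 1.77-fold to 1476 ± 118 CPM, and col-135 rose 4.21-fold to 30.7 ± 3.94 CPM. Among the falls, col-147 went from 93.8 ± 4.85 to 14.3 ± 2.68 CPM (limma, adjusted p = 7.14e-04). The largest falls included col-3 and col-117, from 376 ± 71.3 and 370 ± 71.04 CPM to 48.3 ± 44.6 and 46.5 ± 44.9 CPM, and the group of col-167, col-168, col-169 and col-170, with log2 changes of -3.001, -3.04, -2.97 and -2.94. These 2 groups hold near-identical copies, and their members are uncertain one by one. In mutant replicate 3 col-3 stood at 79.8 CPM and in mutant replicate 4 at 16.8 CPM. Without wild type replicate 4, 6 collagen genes rose and 13 fell, and falls numbered 65 without mutant replicate 3. The collagen list as a whole was not called (camera, adjusted p = 0.163), but it was lower without wild type replicate 3 (adjusted p = 0.0412), without mutant replicates 3 and 4 (1.315e-04 and 0.02549) and with the replicate number as a block (7.63e-09). The separate list of 5 adult-enriched collagens had 1 rise, col-19, by either adjustment (camera, adjusted p = 0.167), and was called without wild type replicate 3 (adjusted p = 0.01700) and with the block (adjusted p = 0.0414).

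**Figure D2:**
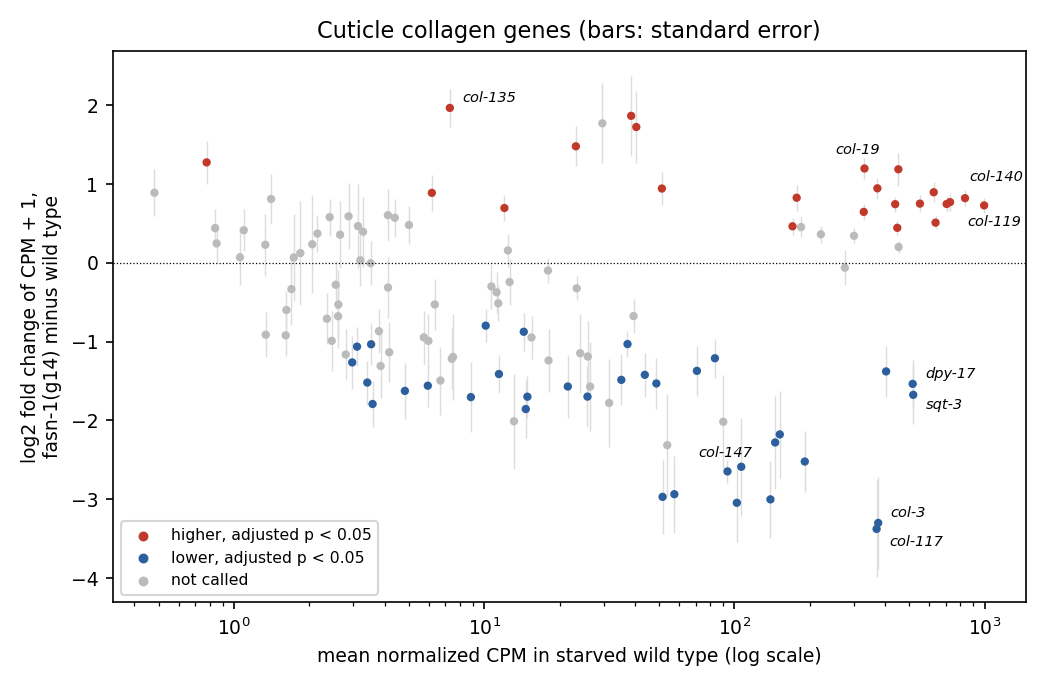
Log2 fold change of CPM + 1 (mutant minus wild type, bars are the SE) of 122 cuticle collagen genes against their mean wild-type CPM on a log axis. The 23 genes that rose include col-19 at 331 CPM, and the 35 that fell reach a log2 change of -3.38.

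Of 34 molting cycle genes measured, 12 fell, 0 rose and 22 did not pass (median log2 change -0.78), and 21 fell and 1 rose when adjusted over the list alone. The mucin-like gene dpy-6 fell from 16.102 ± 3.85 to 2.16 ± 0.673 CPM, and the hedgehog-related genes wrt-1, wrt-2 and qua-1 fell by 1.78, 1.80 and 1.25 on the log2 scale (SE 0.27, 0.29 and 0.19). The list medians of mutant replicates 3 and 4 were -0.53 and -1.08, and 2 genes fell without wild type replicate 4, against 27 without mutant replicate 3. This list was lower by camera (adjusted p = 4.62e-07; adjusted p = 0.621 with an estimated correlation). In the osmotic stress and glycerol list 5 of 17 fell and 2 rose, or 6 and 2 when adjusted over the list alone. Members that fell there include the cuticle furrow collagens dpy-7 and dpy-10 (by 1.37 and 1.21 on the log2 scale) and osr-1, while the myo-inositol transporter gene hmit-1.1 rose 2.303-fold (camera, adjusted p = 0.437), and this list had 0 calls without wild type replicate 4 and 0 rises without wild type replicate 3.

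Of 79 cytosolic ribosomal protein genes measured, 21 fell, 0 rose and 58 did not pass, with a median log2 change of -0.25, and 61 fell when adjusted over the list alone. The paralogs rpl-11.2 and rpl-25.1 fell 1.57-fold and 1.47-fold, and rpl-39 and rps-21 fell 1.31-fold and 1.28-fold. The set was lower by camera (adjusted p = 7.53e-15; adjusted p = 0.612 with an estimated correlation), and 2 and 0 of its members fell without wild type replicates 3 and 4, against 54 and 71 without mutant replicates 3 and 4. Under upper-quartile scaling 62 fell. Of 12 genes on the mitochondrial genome 6 rose, 0 fell and 6 did not pass (median 0.48), with the same counts when adjusted over the list alone. The NADH dehydrogenase subunits ND1 and ND6 rose 1.47-fold and 1.54-fold, and MTCE.16 and MTCE.35 rose 1.55-fold and 1.43-fold. Of these genes 3 and 1 rose without wild type replicates 3 and 4, and 0 in the fit without the trend. That list was higher by camera (adjusted p = 1.71e-04; adjusted p = 0.589 with an estimated correlation). The respiratory chain genes of the nucleus had 0 of 39 past the threshold by either adjustment, with cyc-2.1 at -0.21 and cox-11 at 0.28; their median was -0.01, while camera gave the upward direction (adjusted p = 0.818), which turned downward under upper-quartile scaling, and 4 rose without mutant replicate 3 and 4 fell without mutant replicate 4. Among histones hil-7 fell by 1.33 on the log2 scale (adjusted p = 0.0471; passed in 9 of 17 alternatives, not without wild type replicate 4, and -0.67 without mutant replicate 4) and 50 of 51 did not pass, with 0 when adjusted over the list alone (camera, adjusted p = 0.437) and 13 falls and 6 rises without mutant replicate 3.

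Defence genes moved in both directions. In the intestinal pathogen list 10 of 41 rose and 3 fell, or 11 and 4 when adjusted over the list alone. The saposin-like genes spp-8 and spp-5 and the lysozyme gene ilys-5 rose 2.14-fold, 1.41-fold and 1.42-fold, and C17H12.8 fell from 142 ± 8.78 to 65.5 ± 20.54 CPM. Rises numbered 2 and 4 without wild type replicates 3 and 4, 15 without mutant replicate 4 and 1 in the fit without the trend, and falls numbered 1, 2, 5 and 0 in these fits and 8 without mutant replicate 3. Camera called the list higher (adjusted p = 0.0307; adjusted p = 0.741 with an estimated correlation), a call also lost without mutant replicate 3 (adjusted p = 0.436), at a mean of 5 CPM (0.119) and with the block (0.0773). Of 15 epidermal antimicrobial peptide genes, 3 rose and 4 fell, or 3 and 7 when adjusted over the list alone. In that list nlp-27 and nlp-28 rose 2.98-fold and 2.40-fold, whereas nlp-26 and nlp-33 fell by 2.58 and 1.16 on the log2 scale (camera, adjusted p = 0.339), with 1 rise without wild type replicate 3 and 2 falls without wild type replicate 4, 8 falls without mutant replicate 3 and 5 rises without mutant replicate 4. Detoxification enzymes had 8 rises and 5 falls of 77, or 10 and 6 when adjusted over the list alone, with no call (camera, adjusted p = 0.208), and 3 rose without either wild-type library, against 19 and 14 without mutant replicates 3 and 4, while falls numbered 2 and 1 without wild type replicates 3 and 4 and 11 without mutant replicate 3. The glucuronosyltransferase genes ugt-44 and ugt-47 rose 1.91-fold and 2.17-fold, the glutathione transferase gene gst-5 fell by 0.93 on the log2 scale, and the transporter gene pgp-14 fell from 51.5 ± 3.30 to 8.35 ± 0.907 CPM.

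Among targets induced by the transcription factor DAF-16, ttr-44 rose 1.84-fold, mdl-1 and dod-6 fell by 0.80 and 1.74 on the log2 scale, and 15 of 18 did not pass, with the same counts when adjusted over the list alone. Their median was 0.01 and their mean -0.12 (camera, adjusted p = 0.974). Of 11 targets repressed by DAF-16, 3 rose and 2 fell, or 4 and 3 when adjusted over the list alone, and asm-3 and dod-23 rose while dod-19 fell by 0.83. Their median was -0.23 and their mean 0.06, and camera gave the upward direction (adjusted p = 0.673). In the endoplasmic reticulum unfolded protein list abu-7, abu-8 and abu-11, members of a family also expressed in the pharynx, fell with log2 changes of -1.35, -2.93 and -2.099, sel-1 rose by 0.28, and 24 of 28 did not pass, against 4 falls and 2 rises when adjusted over the list alone. That list had a median of 0.03 and a mean of -0.26 (camera, upward, adjusted p = 0.677). The mitochondrial unfolded protein list had 1 fall among 14 genes, the import gene timm-23 by 0.30, and 0 when adjusted over the list alone (camera, adjusted p = 0.281). In the heat shock list hsp-70 rose 2.35-fold and 15 of 16 did not pass, with the same count over the list alone; its median was -0.07 and its mean 0.05 (camera, downward, adjusted p = 0.818). Of 28 Wnt genes, the ligand gene egl-20 and the Axin gene axl-1 fell by 0.83 and 1.13 by either adjustment and 26 did not pass (camera, adjusted p = 0.637). Without wild type replicate 3, wild type replicate 4, mutant replicate 3 and mutant replicate 4, in this order, rises and falls were 1/2, 1/1, 3/4 and 2/2 for induced targets and 1/1, 1/1, 5/4 and 4/2 for repressed targets of DAF-16. In the same order they were 0/1, 0/1, 6/8 and 5/4 for the endoplasmic reticulum list, 0/0, 0/0, 0/4 and 0/3 for the mitochondrial unfolded protein list, 0/0, 3/0, 3/3 and 1/0 for heat shock, and 0/0, 0/0, 5/13 and 4/4 for Wnt genes.

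Beyond the lists, the largest rise among genes with a symbol was that of scrm-4, a scramblase homolog, from 3.95 ± 1.85 to 43.04 ± 7.45 CPM (log2 change 3.20, SE 0.28; limma, adjusted p = 0.00256). The gene dach-1 rose from 1.83 ± 0.460 to 13.4 ± 3.52 CPM. Other large rises were gipc-2 and nsph-3.2, with log2 changes of 1.92 and 1.87. The gene col-129, at 56.2 and 21.1 CPM in wild type and 79.9 and 207 CPM in the mutant, had a log2 change of 1.87 (SE 0.51; limma, adjusted p = 0.0485), which ranged from 1.18 without wild type replicate 4, where it did not pass, to 2.55 without wild type replicate 3, and it passed in 9 of 17 alternatives. The largest fall was that of srw-85, a chemoreceptor gene of the srw class, from 18.6 ± 1.35 to 0.266 ± 0.102 CPM (log2 change -3.95, SE 0.23; limma, adjusted p = 7.14e-04), a mutant level of 5 and 3 reads. The cilium gene dyf-19 fell from 18.1 ± 4.31 to 1.07 ± 0.4998 CPM. The F-box gene fbxa-192 and the lipase-related gene lips-11 fell from 9.78 ± 0.567 and 10.5 ± 3.29 CPM to 0.194 ± 0.275 and 0.328 ± 0.177 CPM, levels close to the floor.

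**Figure D3:**
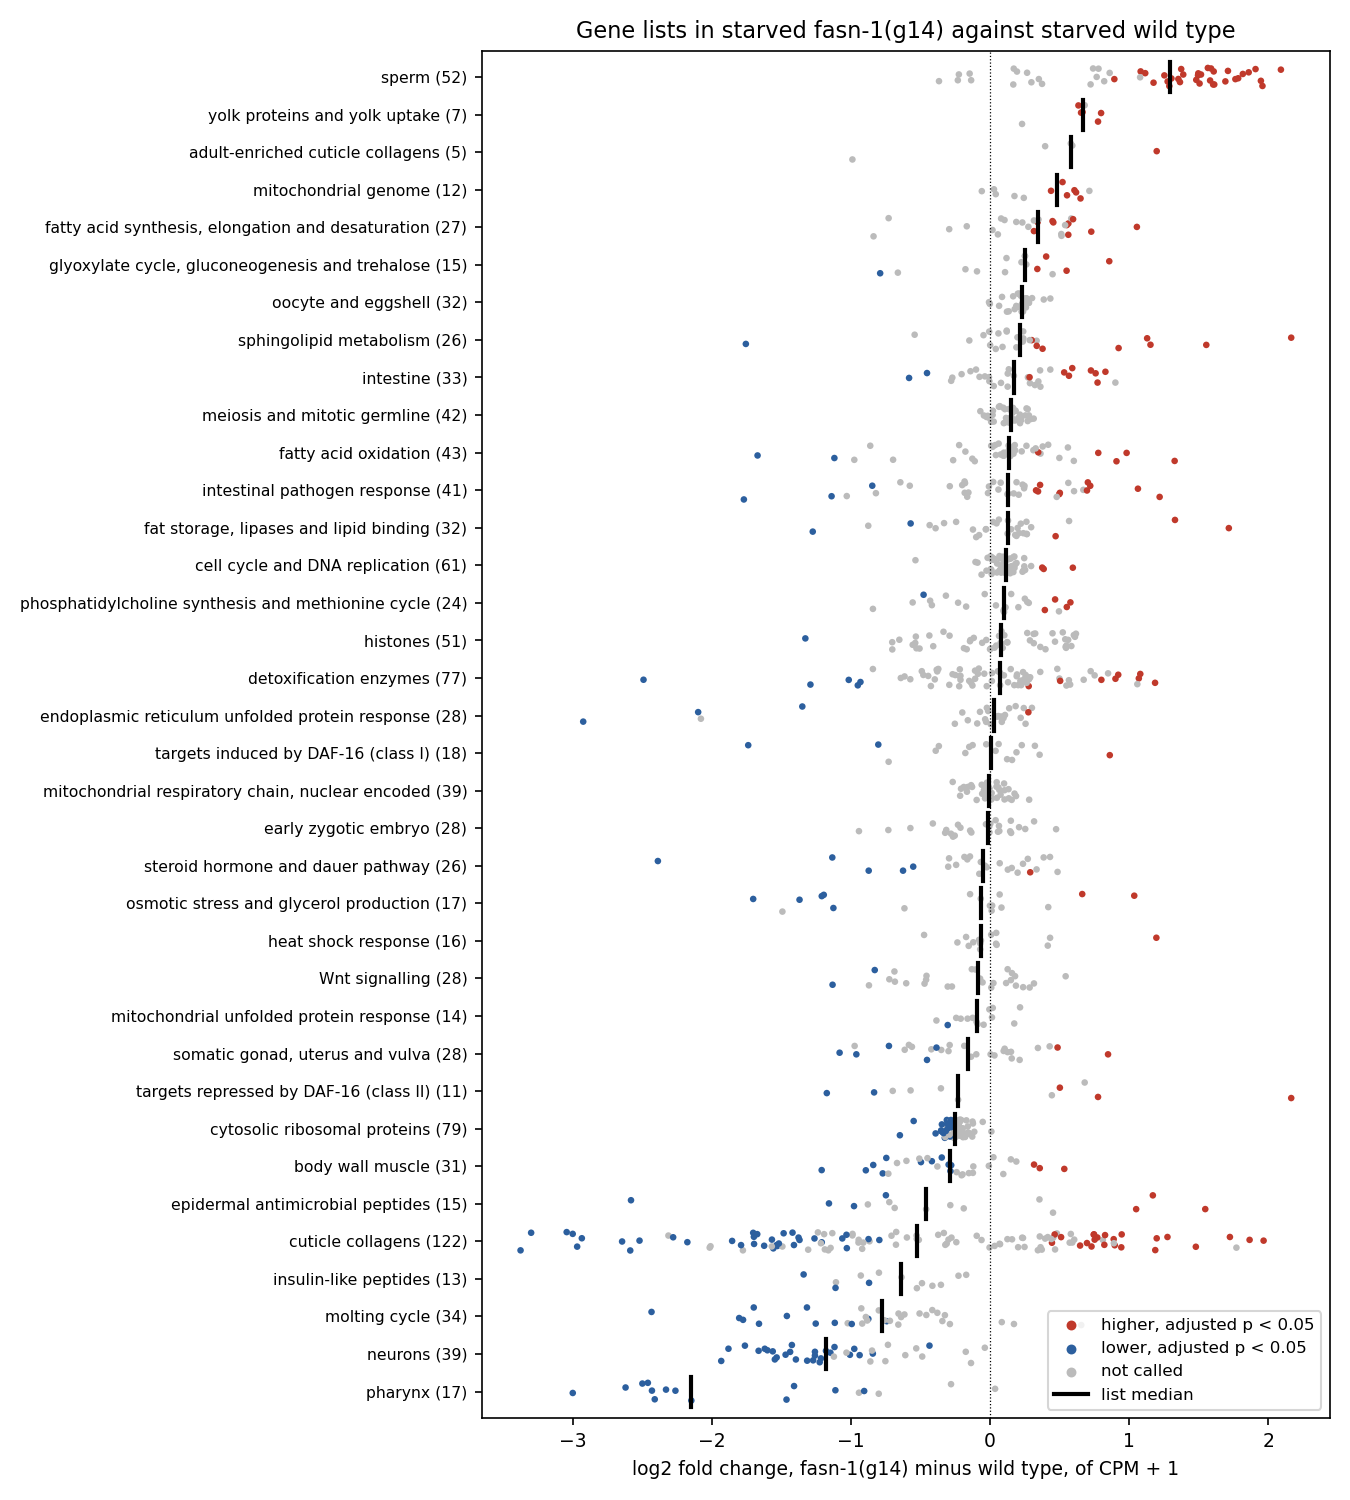
Log2 fold change of CPM + 1 (mutant minus wild type) of each measured member of 36 gene lists, with members tested in brackets, list medians as black bars and color for genes past the threshold. Medians run from -2.15 for the pharynx to 1.297 for sperm.

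Camera with the preset correlation called 12 lists higher and 6 lower out of 36. With an estimated correlation 0 lists passed (0 also at an unadjusted p below 0.05, the smallest unadjusted p being 0.0558). By the directional test of fry 0 lists passed. Its mixed test, which takes changes in either direction, passed for lists such as neurons (fry mixed, adjusted p = 0.0452), pharynx (0.0458), sperm (0.0384) and yolk (0.0243). Lists not called by camera passed it too, such as the nuclear respiratory chain (fry mixed, adjusted p = 0.0452) and detoxification enzymes (0.0135). The mixed test therefore did not set the called lists apart. Of the lists called by camera, those for oocytes (0.324), meiosis (0.255), cell cycle (0.124) and molting (0.0826) did not pass it. The edgeR quasi-likelihood test on the recovered reads called 439 rises and 913 falls, and DESeq2 called 507 and 1057. In the fit without the trend, 11 neuron, 5 pharynx, 2 molting and 0 ribosomal protein genes fell, 19 sperm, 3 yolk and 1 fatty acid synthesis genes rose, and 3 collagen genes rose and 8 fell.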

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

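Of the alternative settings in this part, the crossed pairing alone was chosen after the data were seen. With 2 libraries per group, depth and replicate number left about 41.3% recovery of simulated 1.5-fold changes in genes of at least 5 CPM on average. Genes under about 1 CPM were not tested. The counts of 572 rises and 1386 falls stayed within 1.5 times under both other pseudocounts, no filter, all 3 rescalings, the robust form and DESeq2, and 0 called genes changed sign under any alternative. A mean of at least 5 CPM gave 288 and 509 with 9166 genes tested, and the fit without the trend gave 172 and 545. Falls by edgeR came to 913. With 1 library left out, rises ranged from 151 (without wild type replicate 3) to 2346 (without mutant replicate 3) and falls from 179 (without wild type replicate 4) to 3268 (without mutant replicate 3); the cause was not tested. The fasn-1 log2 change ranged from -0.45 (adjusted p = 1.36e-06) to -0.14 in these fits and passed only without mutant replicate 3 and in the crossed pairing (-0.29, adjusted p = 0.0131). With the replicate number as a block, 626 genes rose and 1872 fell. The numbers are not stated to pair the libraries, and deviations of same-numbered libraries correlated at -0.21 across genes. The crossed pairing, with wild type replicate 3 beside mutant replicate 4, gave 1197 rises and 2310 falls.

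Camera with an estimated correlation and fry called 0 lists higher and 0 lower, against 12 and 6. In the other settings 10 to 13 lists were higher and 5 to 7 lower. Besides yolk, the lists for fat storage, glyoxylate, intestinal pathogens, oocytes, meiosis, sperm and both collagen sets were gained or lost there, as given with each. Among 36 lists, only uncalled ones turned direction, and none became called by turning. Adjusted p under the settings that turned a list are given here, with the range over the 4 fits that leave out 1 library where 1 of those turned it. For DAF-16 induced targets they were 0.8939 by fry, 0.685 at a mean of 5 CPM, 0.6921 with the block, 0.9074 crossed, and 0.4086 to 0.7851 over the leave-out fits. For the nuclear respiratory chain they were 0.8939 by fry, 0.5697 at a mean of 5 CPM, 0.4709 by upper quartile, and 0.1334 to 0.7038. For heat shock they were 0.5774 with the block, 0.9016 by edgeR, and 0.1377 to 0.9047. For histones they were 0.9593 at a mean of 5 CPM and 0.07891 to 0.7228, and for the endoplasmic reticulum list 0.7296 with the block and 0.7228 without mutant replicate 3, with a range of 0.7228 to 0.9094. For early zygotic genes they were 0.9795 by edgeR and 0.1569 to 0.9094, for steroid and dauer genes 0.688 to 0.9702, and for Wnt genes 0.4356 to 0.8748. Among named genes past the threshold, those that passed in the fewest of 17 alternatives were abu-11 (8), hil-7 and col-129 (9 each), and pck-1 and sel-1 (10 each). The uncalled gene col-62 had log2 changes from -0.067 without wild type replicate 4 to 1.251 without wild type replicate 3. The cause of these turns was not tested.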

Other observations

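The tests of gene families, of chromosomes and of the yolk and adult-enriched collagen lists as 1 group were chosen after the results were seen, the last with its gene set and its bound. The most marked single change lay outside the named genes: F15D4.5, an uncharacterized gene on chromosome II (13245376 to 13247774, WBcel235), stood at 2.26 and 2.83 CPM in wild type and at 223 and 230 CPM in the mutant (log2 change 6.01, SE 0.14; limma, adjusted p = 3.34e-06). Its downstream neighbor on the same strand, F15D4.6, rose from 0.523 ± 0.118 to 19.6 ± 0.311 CPM (adjusted p = 7.14e-04), while F15D4.4 on the other side and the other strand had a log2 change of -0.96 (adjusted p = 0.0555). On the falling side C01G10.6 went from 9.36 and 14.1 CPM to 0.338 and 0 CPM. These genes were chosen after their values were seen.

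Among 356 combinations of gene family and direction with at least 8 tested members, 5 families were enriched among rises and 14 among falls (one-sided Fisher's exact test, Benjamini-Hochberg adjusted). The families overlap the fixed lists in part. Of 27 msp genes 26 rose. FMRFamide-like neuropeptide genes (flp) fell in 21 of 30 and other neuropeptide genes (nlp) in 26 of 54, with adjusted p = 1.22e-11 and 2.15e-09. Globin genes (glb) fell in 11 of 25, the chemosensory cilium genes (che) in 6 of 8, the mechanosensory genes (mec) in 7 of 14 and ligand-gated channel genes (lgc) in 10 of 30, whereas phat genes, expressed in the pharynx, fell in 7 of 8. Saposin-like genes (spp) rose in 6 of 21 and aspartyl proteases (asp) in 4 of 11. Without wild type replicates 3 and 4 in turn these counts were 5 and 13 for msp, 9 and 3 for flp, 9 and 3 for nlp, 1 and 0 for glb, 1 and 0 for che, 5 and 2 for mec, 0 and 0 for lgc, 3 and 1 for phat, 1 and 2 for spp and 2 and 1 for asp. Enriched families numbered 2 among rises and 8 among falls without wild type replicate 3, 1 and 1 without wild type replicate 4, and 6 and 36 without mutant replicate 3, where lgc fell in 23, glb in 17 and spp rose in 10. In the fit without the trend spp rose in 1 and asp in 0, che and phat each fell in 3 and mec in 2. Enriched families then numbered 1 among rises and 8 among falls. By DESeq2 glb fell in 5 and lgc in 6, and neither family passed (Fisher's exact test, adjusted p = 0.645 and 0.54). Fisher's exact test takes the genes as independent, which near-identical copies and genes that vary together are not. No family was tested with a correlation between genes.

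On the X chromosome 314 of 1938 tested genes fell, with an odds ratio of 1.80 against the other chromosomes (Fisher's exact test, adjusted p = 3.66e-15). The share of X genes that fell was 5.37%, 2.32% and 37.8% without wild type replicate 3, wild type replicate 4 and mutant replicate 3, and the odds ratio passed in all 17 alternatives, from 1.62 without mutant replicate 4 to 2.099 at a mean of 5 CPM. Rises on X had an odds ratio of 1.297 (adjusted p = 0.0314) that turned to 0.763 (adjusted p = 0.359) without wild type replicate 4 and 0.685 (adjusted p = 2.455e-07) without mutant replicate 3, so no direction is given for them. Other odds ratios past the threshold for rises were 1.42 on IV (adjusted p = 0.00329), 0.748 on II (0.0314), 0.5697 on III (1.11e-04) and 21.9 on the mitochondrial genome (6 of 12 genes, 3.68e-05), and for falls 0.745 on I (8.16e-04) and 0.685 on III (2.32e-05). Without wild type replicate 3 those for II and IV among rises and III among falls did not pass, without wild type replicate 4 those for II and the mitochondrial genome (3 and 1 rises in these 2 fits) and for I and III among falls, without mutant replicate 3 those for II and III among rises, and without mutant replicate 4 that for II. At a mean of at least 5 CPM the odds ratio for rises on IV turned to 0.962 (Fisher's exact test, adjusted p = 0.872), and that on II did not pass (0.729, adjusted p = 0.0933). The odds ratio for falls on I did not pass by edgeR (0.822, adjusted p = 0.108) or DESeq2 (0.882, adjusted p = 0.313). These tests too take genes as independent.

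Neuron and pharynx genes were lower in the mutant. The tables argue against library scaling as the cause, since under 3 other scalings the neuron median stayed at or below -1.17 and the pharynx median at or below -2.14. Of all 12 members of the yolk and adult-enriched collagen lists, 11 lay above 0, and 6 rose and 0 fell. With the replicate number as a block, 1 rose and rol-6 fell. Their median of 0.645 cannot change with that block, since each replicate number stands once in each group. It was 0.623 and 0.685 without wild type replicates 3 and 4 in turn. For the genes they cover, these values mostly lie opposite to what animals not yet adult among the mutants would give. The bound, a median above 0 and more rises than falls in every setting, was chosen after the values were seen. It was met in 17 of 18 settings and not with the block, so this check cannot decide. On the other side, rol-6 lay at -0.99 (adjusted p = 0.0939), and col-62 turned to -0.067 without wild type replicate 4. Hours of age within adulthood, or yolk transcripts diluted by embryo RNA in wild type, were not tested, so the explanation is not excluded. More late embryos or larvae among the wild-type animals may contribute: 10 of 10 genes of late embryos and larval cuticle lay below 0 with a median of -1.46, 7 of them fell (2 without wild type replicate 4), and among the most abundant sqt-3 went from 519 to 180.8 CPM, dpy-17 from 516 to 190 CPM and dpy-10 from 83.6 to 37.04 CPM. The collagens of that list are also in the fixed collagen list, the hatching protease gene hch-1 did not pass (-0.71, adjusted p = 0.145), and neither embryos held in the adult nor hatched larvae on the plate can be singled out. A change of expression in neurons and pharynx of the mutant itself stays open and was not tested.

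Sperm genes were higher in the mutant, a pattern carried by transcripts of a few CPM. Scaling does not account for it, since the median stayed at or above 1.27 under 3 other scalings. The same 12 genes, 11 of them above 0 with a median of 0.645, mostly lie opposite to what animals not yet adult among the mutants would give. They cannot decide this, for the limits given above and since 1 rose and 1 fell with the block. More males among the mutant animals cannot be told apart from the other sources: of 9 genes listed beforehand for male neurons only cwp-4 and cil-7 were measured. Whether these genes are also expressed in hermaphrodites was not examined. Their median of -0.83 met the bound set beforehand against males, but that bound was wrong for 2 genes at 2.32 and 1.27 CPM in wild type, neither of which passed, in libraries where neuron genes fell in general. Hours of age within adulthood, sperm left unused and the genotype itself stay open and were not tested.

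Calls across the genome could in principle reflect variants carried along with fasn-1 on chromosome I. Within 2 Mb of fasn-1, 77 of 713 tested genes were called (10.8%), against 15.3% elsewhere, an odds ratio of 0.668 (95% interval 0.518 to 0.852; Fisher's exact test, p = 8.25e-04), and from 0.402 without wild type replicate 3 to 0.861 without mutant replicate 3 over the alternatives. No excess of calls was thus seen near fasn-1. With 77 of the 1958 calls in this window, effects of linked variants on genes within it could not be the main source at any odds ratio. Falls were also fewer on chromosome I as a whole (odds ratio 0.745), so the low ratio may not be particular to the window. A linked variant that changes genes elsewhere would not raise the local share, so the test cannot decide that case. Single genes in that region, and variants elsewhere in the genome, were not examined.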
